A study of Mus musculus with 15 samples.

How the data were processed

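RNA from hepatocytes of mice was sequenced in 15 libraries. Per the labels, 4 came from wild-type (WT) mice given mineral oil, 3 from WT mice given carbon tetrachloride (CCl4), 4 from ΔEGFR transgenic mice given mineral oil and 4 from ΔEGFR mice given CCl4. Libraries were made with a stranded mRNA kit per the labels' protocols. Reads were aligned to GRCm39 with STAR 2.7.8a and quantified with RSEM 1.3.0 per the submitters' processing notes. The annotation release and the use of strand were not stated. The deposited file of each library lists RSEM expected counts for 56953 Ensembl genes. The same deposited files hold TPM per gene, which the authors' RSEM run derived from those counts. The labels give no animal, batch or replicate number, so replicates were numbered in the order of deposit and the p-values measure the spread between these libraries. No paired analysis was possible because nothing in the labels links a library of one group to a library of another.

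Gene names came from an annotation table of another mouse build, joined by Ensembl ID and used for names alone. It named 52029 IDs (91.4%) and left 4924 without a name, and no coordinates were used. Total counts per library ran from 51.7 to 155.4 M (mega), in 2 ranges of unknown origin, 51.7 to 61.9 M and 96.2 to 155.4 M. Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15, by group), which left 17975 genes. TMM factors scaled the libraries. A model with 1 mean for each of the 4 groups was fitted to all 15 libraries by robust quasi-likelihood, and the Benjamini-Hochberg adjusted p had to be under 0.05 for a gene to be called. The biological coefficient of variation was 50.9%. Log2 CPM for scores and principal components used a prior count of 2. Group values are means ± SD of CPM, and each log2 fold change is given ± its standard error.

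The 5 comparisons were CCl4 against mineral oil in each genotype, ΔEGFR against WT in each treatment, and the interaction of genotype and treatment. The design, the gene lists, the other settings to be tried and the rule for naming genes were fixed before the data were examined. The rule named, per comparison, called genes with a mean log2 CPM of at least 2 and groups that did not overlap, taking the 8 with the largest log2 fold change in each direction and leaving out predicted genes, pseudogenes and mitochondrial genes. It also named up to 4 members per list with the lowest adjusted p, a fixed set of genes for the question of the study, and the EGF receptor family list. The text prints a selection of these.

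The 37 gene lists held 932 entries, of which 4 matched no gene in the files and 15 did not pass the filter. The 36 lists with at least 5 tested members were tested with camera from limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison. The tests were repeated with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. Some lists hold markers of other liver and blood cells, and the mean log2 CPM of such a list served as a score per library. Of 22 stellate cell markers 5 were also in other lists, as were 2 of the endothelial and 3 of the cholangiocyte markers.

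Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no low-count filter, a filter of at least 1 CPM in 3 libraries, a fit of only the groups compared, a test against a fold of 1.5, limma on log2(TPM + 1), a covariate for the markers of other cells, and leaving out each library in turn. No scaling factor, a covariate for depth class, list tests without WT mineral oil replicate 1, list medians under other scalings and list medians without each library were added after the data were seen. Regrouped libraries served to ask how often other splits gave as many called genes.

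The tests were tested on simulated data with this design, with 50 changed genes at each fold. Changed genes were drawn from those with a log2 mean CPM over 2, so recovery at lower counts was not measured. A change of 4-fold was recovered for 84% of genes for CCl4 in WT, 82% for CCl4 in ΔEGFR, 80% for each genotype comparison and 64% for the interaction. A change of 2-fold was recovered for 34%, 30%, 38% (mineral oil), 18% (CCl4) and 8%. Called genes that had not been changed numbered 5 to 7 per comparison with edgeR and 63 to 69 with DESeq2. Simulated genes varied independently of each other, whereas the real libraries also differed in markers of other cells. These counts can therefore understate false calls in the real data. Each simulation also held many changed genes at once, and the unadjusted p that a call needs depends on how many genes change. Recovery can be lower in a comparison with few changed genes, so a lack of called genes does not exclude changes of 4-fold. Expected counts come from reads without molecular identifiers, so counting error alone understates the error. Reads shared by genes of near-identical sequence, such as the Mup and Ugt families, were apportioned by RSEM. Sex chromosome genes were reported as values alone, and exons, isoforms and strands were not analysed here.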

Results

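Messenger RNA of hepatocytes was measured in 15 mouse libraries from 4 groups. CCl4 is a toxin that hepatocytes turn into a reactive radical, and repeated doses scar the liver. Mineral oil is its carrier. ΔEGFR is a transgene named after the epidermal growth factor receptor, and the title of the series places the study in the EGFR pathway of the fibrotic liver. Total counts, in megacounts (M), were 78.62 ± 38 M in WT mineral oil (n = 4), 88.23 ± 58.2 M in WT CCl4 (n = 3), 125.6 ± 18.5 M in ΔEGFR mineral oil (n = 4) and 97.45 ± 32.7 M in ΔEGFR CCl4 (n = 4).

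Egfr, the mouse gene of the receptor, was high in every mineral oil library and low in every CCl4 library. It measured 1150 ± 356 CPM in WT mineral oil (n = 4), 260 ± 87.7 in WT CCl4 (n = 3), 1070 ± 501 in ΔEGFR mineral oil (n = 4) and 195 ± 67.8 in ΔEGFR CCl4 (n = 4). With CCl4 it was 4.42-fold lower in WT (log2 fold change −2.14 ± 0.44, adjusted p = 0.0109) and 5.51-fold lower in ΔEGFR (−2.46 ± 0.40, adjusted p = 0.0112). Without WT CCl4 replicate 3 the WT call was lost (adjusted p = 0.0567, range over left-out libraries 0.00542 to 0.0567). Egfr did not differ by genotype in mineral oil (−0.10 ± 0.38, adjusted p = 0.956) or in CCl4 (−0.42 ± 0.41, adjusted p = 1), and its interaction was −0.32 ± 0.56 (adjusted p = 1). The labels do not give the species or the part of EGFR in the transgene. Its reads may not count toward the mouse gene, so Egfr does not check the genotype labels.

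Along the first principal component, which held 55.7% of the variance, 7 of the 8 mineral oil libraries lay between 3.3 and 176.9 and the 7 CCl4 libraries between −100.6 and −46.8. WT mineral oil replicate 1 was the exception at −62.4, among the CCl4 libraries, and it lay apart from all others on the second component (10.7%). The genotypes overlapped. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.867 to 0.98 for the 21 pairs within a group and 0.863 to 0.984 for the 84 other pairs.

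**Figure D1:**
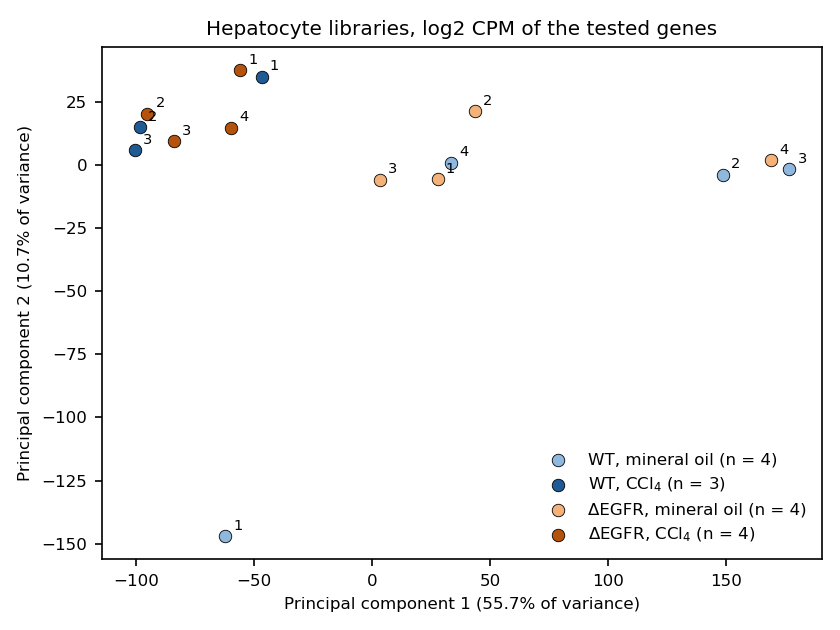
Principal components 1 and 2 of the log2 CPM of all tested genes, with axes giving percent of variance, 1 point per library coloured by group and numbered by replicate. Replicate 1 of WT mineral oil lies at −146.9 on component 2 and at −62.4 on component 1, among the CCl4 libraries. Component 1 parts all other mineral oil libraries from the CCl4 libraries, and within mineral oil it also follows markers of other cells.

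Markers of other liver cells were detected in the hepatocyte libraries, with the widest spread in mineral oil. The macrophage score was 3.87 ± 2.11 mean log2 CPM in WT mineral oil (n = 4) and 7.22 ± 0.71 in WT CCl4 (n = 3), and 3.80 ± 2.12 and 6.96 ± 0.42 in the ΔEGFR groups (n = 4 each). The stellate cell score was 0.86 ± 1.22 and 2.64 ± 1.16 in WT, and 1.26 ± 1.33 and 2.85 ± 0.73 in ΔEGFR. The endothelial score moved less, from 4.14 ± 1.73 to 4.64 ± 0.91 in WT and from 4.11 ± 1.17 to 5.16 ± 0.40 in ΔEGFR. Cholangiocyte markers scored −0.65 ± 1.01 and 1.19 ± 0.42 in WT, and −0.23 ± 1.02 and 1.37 ± 0.80 in ΔEGFR. The other-cell score took in these types and also T and NK cell, B cell and neutrophil markers. It was highest in WT mineral oil replicate 1 (4.11) and lowest in WT mineral oil replicate 3 (−0.47). On the first principal component these lay at −62.4 and 176.9, the ends of the mineral oil range. WT replicate 2 and ΔEGFR replicate 4 in mineral oil, with scores of 0.19 and −0.29, lay at 148.6 and 169.3. The remaining mineral oil libraries, with scores of 1.99 to 2.88, lay at 3.3 to 43.6. The first component therefore cannot be credited to CCl4 apart from other-cell transcripts.

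**Figure D2:**
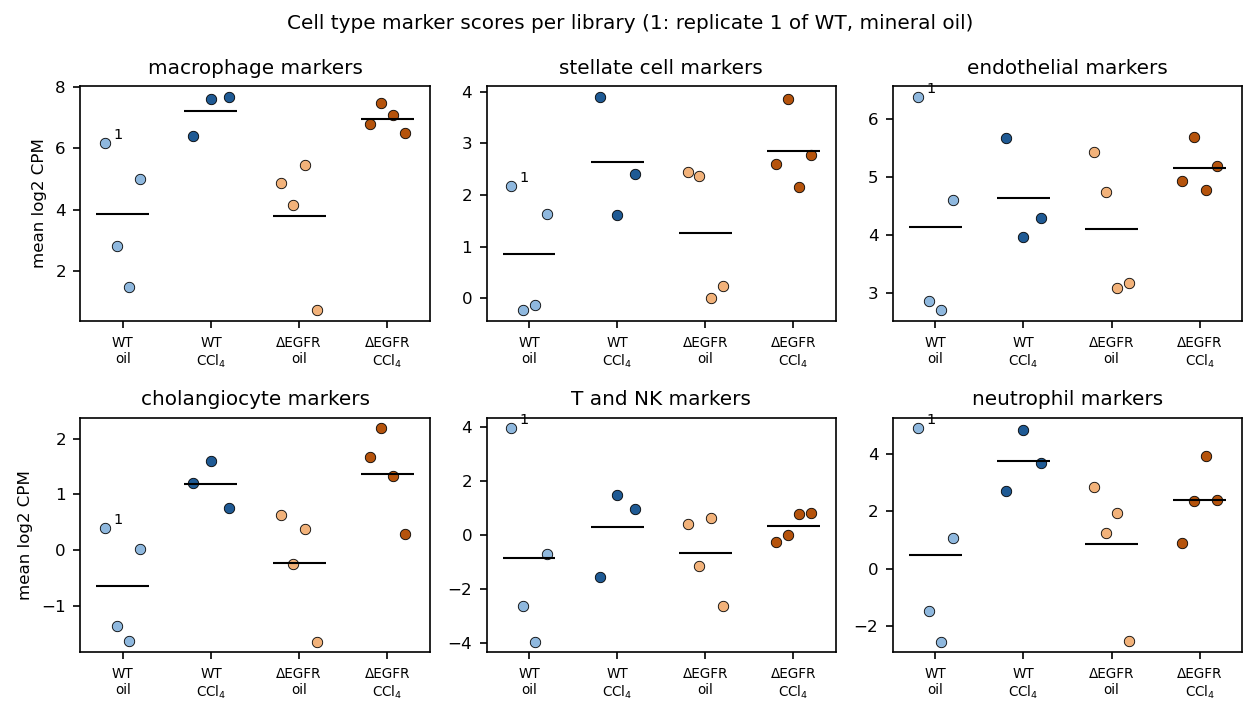
Mean log2 CPM of the markers of 6 cell types in each library (points) by group, with group means as bars. Macrophage markers averaged 7.22 in WT CCl4 against 3.87 in WT mineral oil, and WT mineral oil replicate 1 scored 3.97 for T and NK cells and 4.90 for neutrophils.

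CCl4 against mineral oil in WT asked what the toxin changed in hepatocyte preparations of normal mice. Macrophage genes of tissue damage, collagen genes and Ccnd1 rose, while enzymes of the pericentral zone, bile acid synthesis and complement fell. Gpnmb, a glycoprotein of lipid-laden macrophages, rose from 3.18 ± 3.46 CPM (n = 4) to 2040 ± 1390 (n = 3), a log2 fold change of 9.31 ± 1.48 (adjusted p = 0.0045). Cyp2e1, the cytochrome that activates CCl4, fell from 6430 ± 2230 to 619 ± 336 CPM (−3.38 ± 0.50, adjusted p = 0.00382). Of 17975 genes, 2250 were called, 955 higher and 1295 lower (42.4% higher), and 737 and 770 of these differed by more than 2-fold. At an unadjusted p under 0.05 there were 5187 genes, against 899 by chance.

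In 2070 of the 2250 called genes the WT groups did not overlap; over all genes this held for 24.1%, against 5.7% by chance. The count was 1030 without WT mineral oil replicate 2, 1047 without replicate 3, and 5111 without replicate 1. It was 907 without WT CCl4 replicate 2 and 575 without replicate 3. TMM factors averaged 0.867 ± 0.0931 in WT mineral oil and 1.17 ± 0.16 in WT CCl4. Without a scaling factor the median of all genes was 0.49 log2 in WT and 0.46 in ΔEGFR, and the split became 2326 higher and 515 lower (81.9% higher). With upper-quartile factors the WT median was 0.10. The calls of 76 genes beside Egfr, a selection of those the rule named here that left out Vmn2r3, Mup15 and Mup17, were followed. Of these, 48 kept their call without WT CCl4 replicate 3, 54 without replicate 2 and 67 without replicate 1. Without WT mineral oil replicates 2, 3 and 4 the kept calls numbered 59, 58 and 68.

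Among the largest WT rises were macrophage genes and genes with under 1 CPM in mineral oil. Trem2, a macrophage lipid receptor, rose by 6.15 ± 1.10 (adjusted p = 0.00638), and Mmp12, the macrophage elastase, by 7.75 ± 1.36 (adjusted p = 0.00638). Of 23 macrophage markers 6 rose and 0 fell (6 and 0 adjusted over the list alone), with all 23 log2 fold changes positive and a median of 1.97 (camera adjusted p = 7.3e-09, and adjusted p = 0.51 with an estimated correlation). Syngr1, a vesicle membrane protein, rose by 6.97 ± 0.58 (adjusted p = 0.000302), Emp1, an epithelial membrane protein, by 6.10 ± 1.14 (adjusted p = 0.00734), and Cdh17, the liver-intestine cadherin, by 6.55 ± 1.5 (adjusted p = 0.0164). Fam198b, a Golgi protein gene, rose by 6.04 ± 1.08 (adjusted p = 0.0064). The fetal liver glypican Gpc3 rose by 5.94 ± 0.90 (adjusted p = 0.00382). The median of the macrophage list was 3.16 without WT mineral oil replicate 1.

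Some genes of scar matrix rose in WT together with the stellate cell score. Of 40 matrix genes 16 rose and 0 fell (20 and 1 adjusted over the list alone), with a median of 1.63 (camera adjusted p = 2.43e-10, and adjusted p = 0.475 with an estimated correlation). Col1a1, the main fibrillar collagen chain, rose from 2.47 ± 2.89 to 49.6 ± 36 CPM (4.32 ± 0.90, adjusted p = 0.0114). Col5a2 rose by 3.15 ± 0.53 (adjusted p = 0.00549), Col6a2 by 3.03 ± 0.54 (adjusted p = 0.00638) and elastin, Eln, by 3.76 ± 0.75 (adjusted p = 0.0097). Of 21 stellate cell markers 5 rose and 0 fell (5 and 0 adjusted over the list alone, median 1.52, camera adjusted p = 0.000222, and adjusted p = 0.637 with an estimated correlation). Of 36 TGF-β family genes and targets 4 rose and 1 fell (7 and 2 adjusted over the list alone, median 0.30, camera adjusted p = 0.0253, and adjusted p = 0.637 with an estimated correlation). Ltbp3 and Ltbp2, of the family named for binding latent TGF-β, rose by 4.03 ± 0.75 and 2.82 ± 0.55 (adjusted p = 0.00718 and 0.00914). The decoy receptor Bambi rose by 1.76 ± 0.32 (adjusted p = 0.00638). Tgfbr1 rose by 1.46 ± 0.33 (adjusted p = 0.0149), a call lost without WT CCl4 replicate 2 or 3 (adjusted p at most 0.0826 over all alternatives). Tgfb1 did not pass with edgeR (1.80 ± 0.94, adjusted p = 0.227), but passed under some alternatives (adjusted p from 0.0195 to 0.468 over all of them). The medians were 2.58 for matrix and 0.96 for TGF-β genes without WT mineral oil replicate 1, and 0.99 for matrix, 0.73 for stellate cell and 0.13 for TGF-β genes without WT CCl4 replicate 1.

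Some genes of proliferation, damage and dedifferentiation rose in WT. Ccnd1, cyclin D1 of the G1 phase, rose from 35.6 ± 24.1 to 203 ± 27.1 CPM (2.51 ± 0.46, adjusted p = 0.00671). All 34 cell cycle genes had positive log2 fold changes with a median of 0.97, and 5 rose (6 adjusted over the list alone, camera adjusted p = 0.000199, and adjusted p = 0.637 with an estimated correlation). Among 20 p53 targets 2 rose and 0 fell (2 and 0 adjusted over the list alone, median 0.55, camera adjusted p = 0.0017, and adjusted p = 0.475 with an estimated correlation), led by the death gene Bax (1.22 ± 0.24, adjusted p = 0.00873). Of 34 cytoskeletal and dedifferentiation genes 7 rose and 0 fell (7 and 0 adjusted over the list alone, median 1.08, camera adjusted p = 7.48e-07, and adjusted p = 0.475 with an estimated correlation). Of 14 cholangiocyte markers 4 rose (4 adjusted over the list alone, median 1.52, camera adjusted p = 0.00379, and adjusted p = 0.51 with an estimated correlation), among them the annexin Anxa3 (4.15 ± 0.83, adjusted p = 0.00965). The cytoskeletal median was 2.45 without WT mineral oil replicate 1, and the cell cycle median −0.03 without WT CCl4 replicate 2 and 1.97 without WT mineral oil replicate 4. Of 29 NRF2 targets 2 rose (2 adjusted over the list alone, median 0.29, camera adjusted p = 0.043, and adjusted p = 0.637 with an estimated correlation).

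Some hepatocyte enzymes of both liver zones fell in WT, and CCl4 is activated in the pericentral one. Of 22 pericentral genes 0 rose and 10 fell (0 and 15 adjusted over the list alone, median −1.49, camera adjusted p = 2.43e-10, and adjusted p = 0.228 with an estimated correlation; fry adjusted p = 0.00681). Slc1a2, a glutamate transporter, fell by 7.03 ± 1.18 on the log2 scale (adjusted p = 0.00549) and Oat, ornithine aminotransferase, by 3.93 ± 0.70 (adjusted p = 0.00638). Of 22 periportal genes 0 rose and 8 fell (0 and 12 adjusted over the list alone, median −1.29, camera adjusted p = 1.08e-06, and adjusted p = 0.475 with an estimated correlation), among them Cps1, the entry enzyme of the urea cycle (−1.53 ± 0.30, adjusted p = 0.00926). Of 35 phase I enzymes 1 rose and 14 fell (3 and 22 adjusted over the list alone, median −1.36, camera adjusted p = 1.82e-10, and adjusted p = 0.228 with an estimated correlation), among them the cytochrome Cyp2d9 (−1.88 ± 0.28, adjusted p = 0.00382) and the carboxylesterase Ces3a (−1.76 ± 0.31, adjusted p = 0.00638). Of 20 hepatocyte identity genes 0 rose and 4 fell (0 and 9 adjusted over the list alone, median −0.76, camera adjusted p = 1.45e-05, and adjusted p = 0.52 with an estimated correlation). Alb, albumin, did not pass (−0.41 ± 0.44, adjusted p = 0.572), and was 0.06 with limma on TPM.

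**Figure D3:**
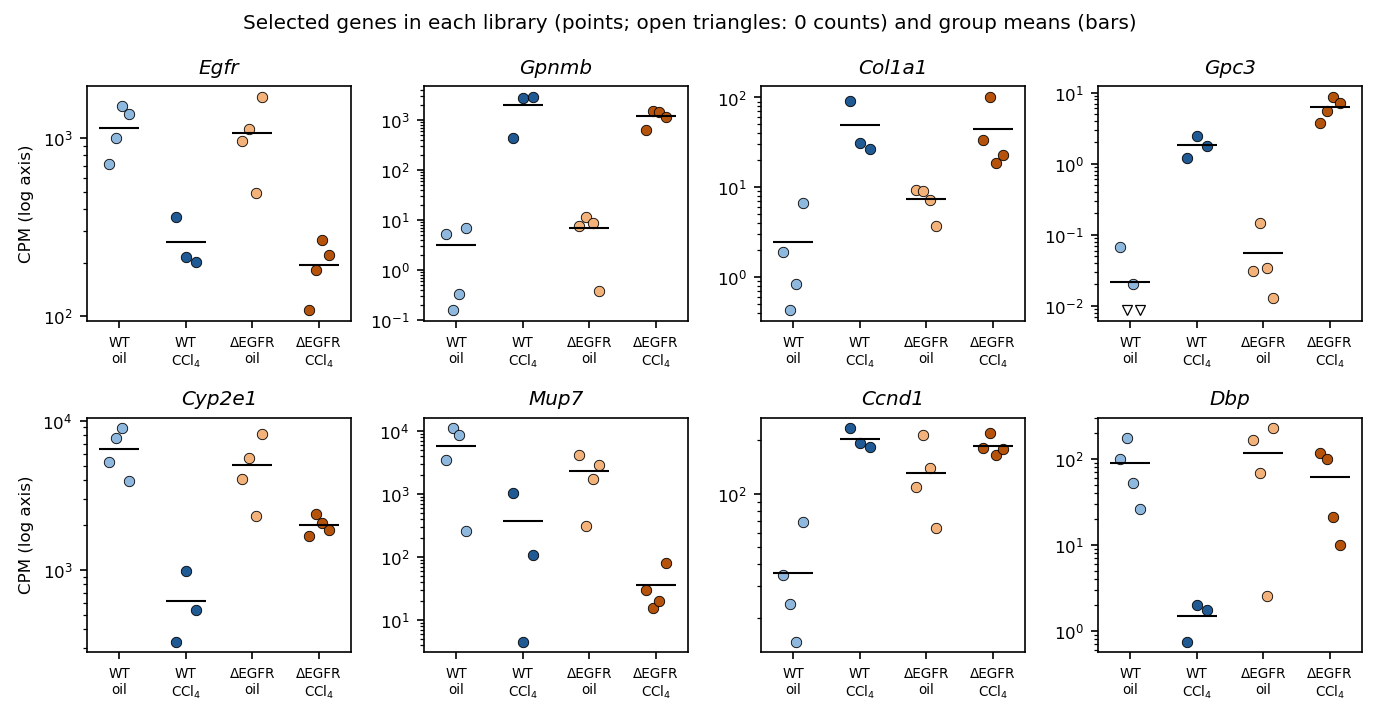
CPM on a log axis for 8 genes in each library (points, open triangles for 0 counts) by group, with group means as bars. Cyp2e1 averaged 619 CPM in WT CCl4 and 1990 in ΔEGFR CCl4, and Dbp lay between 0.742 and 1.98 CPM in the 3 WT CCl4 libraries.

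Secretory and bile acid genes of WT hepatocytes fell too. All 37 complement and coagulation genes had negative log2 fold changes (median −1.04), and 15 fell (25 adjusted over the list alone, camera adjusted p = 2.13e-17, and adjusted p = 0.475 with an estimated correlation). C6 and C8b, of the membrane attack complex, fell by 1.93 ± 0.30 and 2.01 ± 0.32 (adjusted p = 0.00426 and 0.00463). Susd4, a complement inhibitor, fell by 7.09 ± 1.01 (adjusted p = 0.00352). Of 24 bile acid genes 0 rose and 9 fell (1 and 15 adjusted over the list alone, median −1.13, camera adjusted p = 7.3e-09, and adjusted p = 0.228 with an estimated correlation). Baat, which conjugates bile acids, fell by 1.23 ± 0.19 (adjusted p = 0.00444), and the hydroxylases Cyp7b1 and Cyp8b1 by 3.96 ± 0.66 and 3.27 ± 0.56 (adjusted p = 0.00549 and 0.00553). Of 29 acute phase genes 0 rose and 3 fell (0 and 3 adjusted over the list alone, median −0.76, camera adjusted p = 0.00028, and adjusted p = 0.637 with an estimated correlation), and the median was −1.39 without WT CCl4 replicate 1 and −0.40 without replicate 3.

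Some growth hormone, sex-biased and clock genes fell in WT. Of 24 genes driven by growth hormone or sex 1 rose and 10 fell (1 and 13 adjusted over the list alone, median −1.74, camera adjusted p = 5.27e-07, and adjusted p = 0.228 with an estimated correlation). Mup19, a urinary pheromone carrier, fell by 12.67 ± 2.12 (adjusted p = 0.00549), from 1290 ± 1350 to 0.205 ± 0.151 CPM, and Selenbp2, a selenium-binding protein, by 4.32 ± 0.63 (adjusted p = 0.00363). Of 20 clock genes 0 rose and 7 fell (1 and 11 adjusted over the list alone, median −1.30, camera adjusted p = 0.00159, and adjusted p = 0.331 with an estimated correlation). Dbp, a transcription factor at the output of the clock, fell by 5.90 ± 1.41 (adjusted p = 0.0195), a call lost without any 1 of WT CCl4 replicates 1, 2 and 3 (adjusted p at most 0.0851 over all alternatives). Sex chromosome genes, 4 in number, did not pass (median −0.37).

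Lipid genes moved both ways in WT. Plin2, the coat of lipid droplets, rose by 1.57 ± 0.24 (adjusted p = 0.00429), and Fitm1, which helps form droplets, fell by 3.95 ± 0.53 (adjusted p = 0.00344). Of 30 lipogenesis genes 2 rose and 5 fell (3 and 8 adjusted over the list alone, median −0.43, camera adjusted p = 0.0598). Of 30 fatty acid oxidation genes 2 rose and 5 fell (4 and 6 adjusted over the list alone, median −0.42, camera adjusted p = 0.127), a list whose median, mean and test differed in sign and whose median was 0.03 without a scaling factor. The ω-hydroxylase Cyp4a32 fell by 1.67 ± 0.33 (adjusted p = 0.00875). All 30 oxidative phosphorylation genes were negative (median −0.47), with 3 falling (10 adjusted over the list alone, camera adjusted p = 1.45e-06, and adjusted p = 0.637 with an estimated correlation). Of 26 cholesterol synthesis genes 1 fell (1 adjusted over the list alone, median −0.25, or 0.16 without a scaling factor; camera adjusted p = 0.0665). Of 20 glycolysis genes 1 rose and 1 fell (1 and 1 adjusted over the list alone, median 0.08, camera adjusted p = 0.416).

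Lists of the EGF receptor family and of signalling did not pass in WT. Of 23 family genes 3 rose and 3 fell (3 and 3 adjusted over the list alone, median 0.38, camera adjusted p = 0.878). Besides Egfr, the receptor Erbb4 fell by 4.35 ± 0.93 (adjusted p = 0.0126) and Lrig1, which restrains the receptors, by 1.08 ± 0.19 (adjusted p = 0.00638). Erbb4 had few counts, with 1.87 ± 0.739 CPM in WT mineral oil and 0.0865 ± 0.0772 in WT CCl4. Its log2 fold change ran from −5.04 to −0.29 over all alternatives. The shedding protease Adam10 rose by 0.97 ± 0.26 and Adam17 by 1.07 ± 0.28 (adjusted p = 0.0308 and 0.0264), as did the adaptor Grb2 (0.73 ± 0.17, adjusted p = 0.0187). These 3 calls were each lost without WT mineral oil replicate 2 or 3 or WT CCl4 replicate 2 or 3, with an adjusted p of at most 0.233, 0.173 and 0.417 over all alternatives. Erbb3 did not pass with edgeR (−1.11 ± 0.42, adjusted p = 0.0967), but passed under some alternatives (adjusted p from 0.0141 to 0.457 over all of them). Of 25 MAPK pathway genes 2 rose (2 adjusted over the list alone, median 0.21, camera adjusted p = 0.205), Ccnd1 and the ETS factor Etv4 (4.16 ± 0.85, adjusted p = 0.0108). Of 17 YAP targets 2 rose and 2 fell (3 and 2 adjusted over the list alone, median 0.37, camera adjusted p = 0.205). Of 54 secreted ligand genes 7 rose and 4 fell (8 and 5 adjusted over the list alone, median −0.04, or 0.30 without a scaling factor and 0.65 without WT mineral oil replicate 1; camera adjusted p = 0.566), with signs that differed between median, mean and test. Without WT mineral oil replicate 1 the medians were 0.69 for the family, 0.82 for MAPK and 0.98 for YAP genes. Vegfa, the vascular growth factor, did not pass (−0.77 ± 0.36, adjusted p = 0.173).

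Inflammation, stress and blood cell lists of WT gave few called members. Of 36 chemokine and cytokine genes Cxcl5 alone rose, and none did adjusted over the list alone (median 0.23, camera adjusted p = 0.0487, and adjusted p = 0.766 with an estimated correlation). Cxcl5, a neutrophil attractant, rose by 4.37 ± 1.19 (adjusted p = 0.0315), a call lost without WT mineral oil replicate 2, 3 or 4 or WT CCl4 replicate 1, 2 or 3 (adjusted p at most 0.125 over all alternatives). Medians were 0.04 for 30 interferon-stimulated genes (1 rose), 0.54 for 21 unfolded protein response genes (1 fell), and −0.12 for 22 dissociation and heat shock genes (0 called; 0.21 without a scaling factor). Their camera adjusted p-values were 0.937, 0.109 and 0.878, and adjusted over the list alone 0 of these genes were called. Of 12 neutrophil markers 2 rose (3 adjusted over the list alone), with a median of −1.18 against a test that pointed up (camera adjusted p = 0.0116, and adjusted p = 0.637 with an estimated correlation). Medians of uncalled marker lists were −1.56 for T and NK cells (camera adjusted p = 0.872), 0.55 for B cells (0.0755), −1.36 for red blood cells (0.446; 1 fell) and −0.12 for endothelium (0.57; 0.12 without a scaling factor). For T and NK cells, endothelium and the dissociation list the median and the test also differed in sign. The negative medians rested on WT mineral oil replicate 1. Without it the medians were 2.61 for T and NK cells, 3.48 for B cells, 3.69 for red blood cells, 1.10 for endothelium, 4.16 for neutrophils, 0.49 for dissociation and 1.90 for chemokine genes (−0.03 with replicate 2 left out instead).

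CCl4 against mineral oil in ΔEGFR asked for the same response with the transgene. Gpnmb rose from 7.09 ± 4.74 to 1200 ± 414 CPM (n = 4 each), a log2 fold change of 7.40 ± 1.35 (adjusted p = 0.0178). Gpc3 rose by 6.73 ± 0.87 (adjusted p = 0.0048) and Syngr1 by 6.12 ± 0.54 (adjusted p = 0.000638), while Slc1a2 fell by 6.66 ± 1.02 (adjusted p = 0.00991) and Baat by 1.25 ± 0.18 (adjusted p = 0.00874). The Gpnmb call was lost without ΔEGFR CCl4 replicate 2 (adjusted p = 0.053, the highest over all alternatives). Of 17975 genes 746 were called, 319 higher and 427 lower (42.8% higher), of which 293 and 291 differed by more than 2-fold. At an unadjusted p under 0.05 there were 4447 genes, against 899 by chance. In 721 of the called genes the ΔEGFR groups did not overlap; over all genes this held for 21.6%, against 2.9% by chance.

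The ΔEGFR count rested on many single libraries. It was 289, 182 and 94 without ΔEGFR mineral oil replicates 1, 2 and 4, and 101, 75 and 129 without ΔEGFR CCl4 replicates 1, 2 and 3. WT libraries share the model, and it was 2145 without WT mineral oil replicate 1, 493 without WT mineral oil replicate 4 and 396 without WT CCl4 replicate 2. Without a scaling factor 997 genes were higher and 183 lower (84.5% higher), and with upper-quartile factors 315 were higher and 275 lower (53.4% higher). The calls of 52 genes beside Egfr, a selection of those the rule named here that left out Mup12, Mup14, Mup16 and Mup17, were followed. Of these, 15 kept their call without ΔEGFR CCl4 replicate 2, 18 without replicate 1 and 22 without replicate 3. For ΔEGFR mineral oil replicates 4, 2 and 1 the kept calls numbered 19, 25 and 27. Among these 52 genes, Syngr1, Gpc3, Slc1a2, Oat, Baat, Cyp7b1, C6, C8b, Fitm1, Susd4, Aldh1l2, Cyp1a1, Pigr, Cyp4a12a and Nudt7 kept theirs without any 1 library.

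Macrophage and stellate cell markers were again higher as lists with CCl4 in ΔEGFR, by camera with the preset correlation alone. Of 23 macrophage markers 2 rose (13 adjusted over the list alone), all 23 were positive and the median was 2.46 (camera adjusted p = 1.73e-11, and adjusted p = 0.547 with an estimated correlation). Aldh1l2, a mitochondrial folate enzyme, rose by 5.26 ± 0.79 (adjusted p = 0.00944), and Cyp1a1, a cytochrome of aryl hydrocarbon signalling, by 3.06 ± 0.49 (adjusted p = 0.0107). Of 40 matrix genes 4 rose and 0 fell (13 and 2 adjusted over the list alone, median 1.79, camera adjusted p = 4.55e-08, and adjusted p = 0.573 with an estimated correlation). Col1a1 did not pass with edgeR (2.60 ± 0.81, adjusted p = 0.0817), but passed under some alternatives (adjusted p from 0.00907 to 0.463 over all of them). Its interaction was −1.73 ± 1.12 (adjusted p = 1). Stellate cell markers (0 called, 4 rose adjusted over the list alone) had a median of 0.92 (camera adjusted p = 0.000224, and adjusted p = 0.661 with an estimated correlation). TGF-β genes had a median of 0.57, with 2 rising and 1 falling (3 and 1 adjusted over the list alone, camera adjusted p = 0.0361, and adjusted p = 0.661 with an estimated correlation). Tgfb1 did not pass (1.98 ± 0.90, adjusted p = 0.197). With ΔEGFR CCl4 replicate 2 left out the median was 0.48 for stellate cell and 0.21 for TGF-β genes.

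Next were growth, structure and further marker lists in ΔEGFR. The cell cycle list had 1 rising gene (0 adjusted over the list alone, median 0.45, camera adjusted p = 0.0116, and adjusted p = 0.818 with an estimated correlation), and Ccnd1 did not pass (0.51 ± 0.42, adjusted p = 0.469; interaction −2.01 ± 0.61, adjusted p = 1). Cytoskeletal genes had 1 rising member, Gpc3 (1 adjusted over the list alone, median 1.33, camera adjusted p = 0.000152, and adjusted p = 0.636 with an estimated correlation). p53 targets had 0 called (0 adjusted over the list alone, median 0.53, camera adjusted p = 0.0206, and adjusted p = 0.652 with an estimated correlation). Cholangiocyte markers had 1 rising member (4 adjusted over the list alone, median 1.70, camera adjusted p = 0.00109, and adjusted p = 0.554 with an estimated correlation). Endothelial and B cell markers had 0 called (0 adjusted over the list alone) and medians of 0.65 and 1.94 (camera adjusted p = 0.0151 and 0.00884; 0.818 and 0.661 with an estimated correlation). With any 1 library left out the median ran from −0.04 to 1.08 for cell cycle, 1.07 to 2.08 for cholangiocyte and 0.35 to 1.23 for endothelial genes.

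Hepatocyte functions fell in ΔEGFR as lists. Of 37 complement genes 16 fell (32 adjusted over the list alone), 0 were positive and the median was −1.10 (camera adjusted p = 1.13e-25, and adjusted p = 0.484 with an estimated correlation; fry adjusted p = 0.0254). Of 24 bile acid genes 1 rose and 6 fell (1 and 13 adjusted over the list alone, median −0.94, camera adjusted p = 2.4e-09, and adjusted p = 0.301 with an estimated correlation; fry adjusted p = 0.01). Cyp7b1 fell by 3.84 ± 0.58 (adjusted p = 0.00944). Of 24 growth hormone and sex-biased genes 1 rose and 9 fell (1 and 15 adjusted over the list alone, median −1.30, camera adjusted p = 1.92e-08, and adjusted p = 0.201 with an estimated correlation; fry adjusted p = 0.00471), with the male-biased cytochrome Cyp4a12a down by 3.03 ± 0.48 (adjusted p = 0.0105). Mup19 fell by 8.46 ± 1.56 (adjusted p = 0.0185), a call lost without ΔEGFR CCl4 replicate 2 (adjusted p = 0.0756, the highest over all alternatives). Of 22 periportal genes 8 fell (1 rose and 15 fell adjusted over the list alone, median −1.10, camera adjusted p = 9.53e-10, and adjusted p = 0.5 with an estimated correlation), among them Pigr, the carrier of immunoglobulin A (−1.95 ± 0.31, adjusted p = 0.0107). Of 29 acute phase genes 4 fell (19 adjusted over the list alone, median −1.27, camera adjusted p = 2.69e-10, and adjusted p = 0.5 with an estimated correlation).

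Pericentral genes fell as a list in ΔEGFR too. Of 22 genes 1 rose and 4 fell (1 and 7 adjusted over the list alone, median −0.61, camera adjusted p = 0.000194, and adjusted p = 0.573 with an estimated correlation). Cyp2e1 did not pass with edgeR (−1.33 ± 0.41, adjusted p = 0.0815), but passed under some alternatives (adjusted p from 0.0277 to 0.408 over all of them). Its interaction was 2.05 ± 0.61 (adjusted p = 1), against a median interaction of the list of 0.76 (camera adjusted p = 2.55e-08, and adjusted p = 0.593 with an estimated correlation). Oat fell by 3.89 ± 0.62 (adjusted p = 0.0107). Phase I enzymes had 1 rising and 10 falling members (4 and 17 adjusted over the list alone, median −1.02, camera adjusted p = 2.4e-06, and adjusted p = 0.519 with an estimated correlation). Identity genes had 1 falling member (5 adjusted over the list alone, median −0.58, camera adjusted p = 8.82e-06, and adjusted p = 0.584 with an estimated correlation). Oxidative phosphorylation genes had 0 called (0 adjusted over the list alone, median −0.43, or 0.04 without a scaling factor; camera adjusted p = 9.74e-08, and adjusted p = 0.636 with an estimated correlation). Cholesterol genes had 1 falling (1 adjusted over the list alone, median −0.22, or 0.25 without a scaling factor and −0.59 without ΔEGFR CCl4 replicate 4; camera adjusted p = 0.0201, and adjusted p = 0.818 with an estimated correlation). Clock genes had 0 called (0 adjusted over the list alone, median −0.33, or 0.09 without a scaling factor; camera adjusted p = 0.195).

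The EGF receptor family had 1 rising and 2 falling genes in ΔEGFR (4 and 3 adjusted over the list alone, median 0.11, camera adjusted p = 0.847), and MAPK genes 1 rising (1 adjusted over the list alone, median 0.19, camera adjusted p = 0.491). Medians of other uncalled lists were 0.45 for YAP targets (camera adjusted p = 0.0651), 0.21 for chemokines (0.0893), 0.18 for interferon-stimulated genes (0.528) and 0.17 for secreted ligands (0.957). They were 0.56 for T and NK cell (0.274), 1.01 for neutrophil (0.0895) and 0.37 for red blood cell markers (0.396). NRF2 targets (−0.06, 0.988), unfolded protein response (−0.21, 0.437), dissociation (−0.19, 0.957), lipogenesis (−0.34, 0.0601), fatty acid oxidation (−0.36, 0.195) and glycolysis genes (−0.04, 0.882) had negative medians. Without a scaling factor those were 0.37, 0.24, 0.31, 0.16, 0.10 and 0.40. Signs differed between median, mean and test for NRF2, fatty acid oxidation, glycolysis, ligand and red blood cell genes. Fitm1 fell by 3.58 ± 0.46 (adjusted p = 0.0048), and the sex chromosome genes had a median of −0.35.

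The changes with CCl4 in both genotypes pointed mostly the same way. Pearson's r of the log2 fold changes across 17975 genes, which are not independent replicates, was 0.721, and 76.4% had the same sign. Of genes called in WT 98.8% had the same sign in ΔEGFR. Gpnmb, Gpc3 and Syngr1 were among 270 genes called higher in both, against 16.9 expected if the calls in the 2 genotypes were independent. Slc1a2, Oat, Baat and C6 were among 352 called lower in both, against 30.8 expected in the same way. The calls were not independent, since both comparisons used 1 model with a shared spread per gene. Other-cell scores were also higher on average with CCl4 in both genotypes. With the covariate for markers of other cells the shared genes numbered 29 higher and 37 lower, against 0.7 and 1 expected. Leaving out 1 library moved these counts widely, to 34 and 40 without ΔEGFR CCl4 replicate 2, 38 and 53 without ΔEGFR mineral oil replicate 4, and 849 and 1003 without WT mineral oil replicate 1. No gene was called in opposite directions by edgeR, while 1 was by DESeq2 and 1 by limma on log2(TPM + 1).

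**Figure D4:**
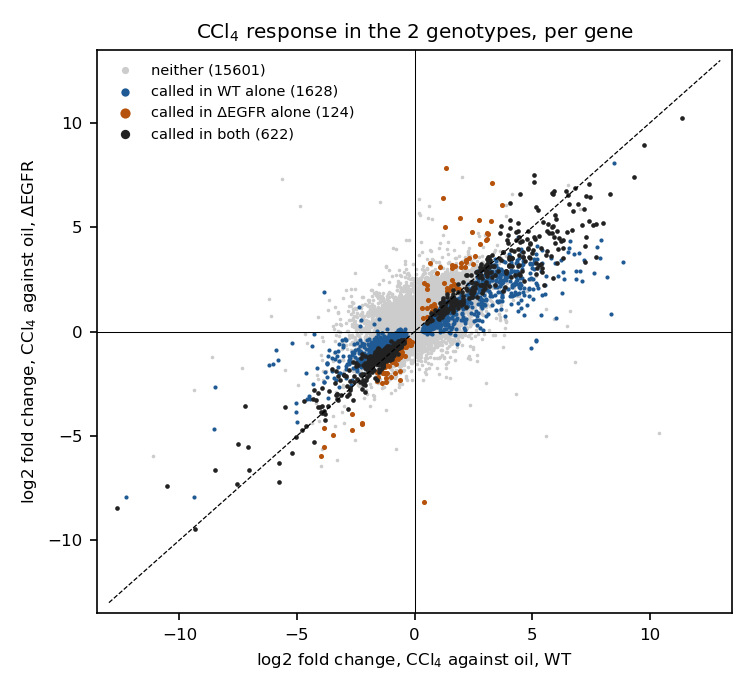
Log2 fold change with CCl4 per gene in WT (horizontal) and ΔEGFR (vertical), coloured by call, with a dashed line of equal change. In both genotypes 622 genes were called, against 1628 in WT alone and 124 in ΔEGFR alone.

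ΔEGFR against WT in mineral oil asked what the transgene changed without injury. No gene passed with edgeR, where the lowest adjusted p was 0.636 and 1197 genes had an unadjusted p under 0.05, against 899 by chance. DESeq2, with 63 unchanged genes among 230 called on simulated data (edgeR 7 among 154), called 9 genes here, and limma 0. Ccnd1, the cyclin that rose with CCl4 in WT, was among those 9. It measured 35.6 ± 24.1 CPM in WT (n = 4) and 132 ± 62.6 in ΔEGFR (n = 4), a log2 fold change of 1.88 ± 0.43 (edgeR adjusted p = 0.713, from 0.0488 to 1 over all alternatives). Groups did not overlap in 2.7% of genes, against 2.9% by chance, and leaving out any 1 library gave 0 calls. Depth nearly followed genotype here: 3 of the 4 WT libraries had 56.9 to 61.9 M counts, WT replicate 1 had 135.5 M and all 4 ΔEGFR libraries had 98.6 to 140.6 M. With depth class in the model 0 genes passed and 2351 had an unadjusted p under 0.05.

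As lists, cell cycle genes were higher in ΔEGFR mineral oil, and all list results here were lost with an estimated correlation (adjusted p = 0.95). In 33 of 34 cell cycle genes the log2 fold change was positive, with a median of 1.53 (camera adjusted p = 1.3e-12; 0 genes over all genes and 1 adjusted over the list alone). Mcm2, of the replicative helicase, had 1.03 ± 0.40 (adjusted p = 0.713). NRF2 targets (median 0.29, camera adjusted p = 0.00111), p53 targets (0.41, 0.00111), matrix (0.37, 0.00557), cytoskeletal (0.29, 0.00296), fatty acid oxidation (0.19, 0.00278) and oxidative phosphorylation genes (0.12, 0.0205) were higher. Krt8 and Krt18, keratins of the hepatocyte cytoskeleton, had 1.32 ± 0.46 and 1.29 ± 0.47 (adjusted p = 0.713 for both). Interferon-stimulated (−0.39, 0.00228) and dissociation genes (−0.59, 0.0324) were lower. Mx2, an antiviral GTPase, had −1.26 ± 0.50 (adjusted p = 0.713). Beside these lists the medians of blood cell markers were −2.18 for T and NK cells, −2.57 for neutrophils and −2.33 for red blood cells, none of which passed. Without WT mineral oil replicate 1 the signs of these marker medians turned, to 1.82, 2.34 and 2.82. So did those of oxidative phosphorylation (−0.02, adjusted p = 0.272), dissociation (0.39, adjusted p = 0.0912) and interferon-stimulated genes (0.01, adjusted p = 0.94). The median without it was 0.87 for matrix, 1.10 for cytoskeletal, 0.27 for p53 and 0.11 for fatty acid oxidation genes. With any 1 library left out the median ran from 0.77 to 2.45 for cell cycle, 0.01 to 0.87 for matrix, −0.01 to 1.10 for cytoskeletal, 0.16 to 0.53 for NRF2, 0.25 to 0.64 for p53 and 0.05 to 0.30 for fatty acid oxidation genes.

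ΔEGFR against WT in CCl4 asked what the transgene changed during injury. No gene passed with edgeR, where 411 genes had an unadjusted p under 0.05 against 899 by chance, and limma called 0. DESeq2, with 69 unchanged genes among 236 called on simulated data (edgeR 6 among 146), called 1, Dbp (log2 fold change 5.38, adjusted p = 0.00589). In edgeR Dbp had 5.39 ± 1.38 (adjusted p = 1, from 0.00589 to 1 over all alternatives). Cyp2e1 measured 619 ± 336 CPM in WT (n = 3) and 1990 ± 290 in ΔEGFR (n = 4), a log2 fold change of 1.69 ± 0.46 (edgeR adjusted p = 1). Groups did not overlap in 5.1% of genes, against 5.7% by chance, and leaving out any 1 library gave 0 calls.

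Pericentral genes were higher as a list in ΔEGFR CCl4. Of 22 pericentral genes 20 had positive log2 fold changes, with a median of 0.72 (camera adjusted p = 5.11e-14, and adjusted p = 0.164 with an estimated correlation; 0 over all genes and 3 adjusted over the list alone). Cyp1a2, a pericentral cytochrome, had 1.25 ± 0.35 and the Wnt target Axin2 1.02 ± 0.31 (adjusted p = 1 for both). Clock genes had a median of 0.54 and 5 called adjusted over the list alone (camera adjusted p = 4.13e-06, and adjusted p = 0.164 with an estimated correlation), among them the clock outputs Tef (2.51 ± 0.69) and Per3 (3.66 ± 1.10, adjusted p = 1 for both over all genes). The mean log2 CPM of 10 clock genes in the phase of Dbp was 2.43 to 3.34 in WT CCl4 and 4.10 to 5.40 in ΔEGFR CCl4. The labels give no collection time. A different time of day in WT CCl4 therefore cannot be told apart from an effect of the transgene on clock genes, Dbp included, here or in the interaction. Phase I (0.63, camera adjusted p = 2.08e-07), cell cycle (1.01, 2.88e-06), fatty acid oxidation (0.35, 1.49e-06) and oxidative phosphorylation genes (0.17, 0.000115) were higher. With an estimated correlation their adjusted p-values were 0.607, 0.848, 0.751 and 0.951. Lipogenesis (0.23, 0.00507), bile acid (0.21, 0.0345) and endothelial genes (0.31, 0.0245) were higher too (adjusted p = 0.751, 0.892 and 0.951 with an estimated correlation). With any 1 library left out the medians ran from 0.43 to 1.02 for pericentral, 0.39 to 0.68 for clock, 0.18 to 0.91 for phase I, 0.23 to 2.15 for cell cycle, 0.14 to 0.53 for fatty acid oxidation, 0.08 to 0.26 for oxidative phosphorylation, 0.05 to 0.33 for lipogenesis, 0.05 to 0.27 for bile acid and −0.01 to 1.18 for endothelial genes.

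The list of 25 MAPK pathway genes, with Fos at −1.69 ± 0.75 (adjusted p = 1), was lower in ΔEGFR CCl4 (median −0.42, camera adjusted p = 5.89e-05). Acute phase genes had a median of −0.75 (camera adjusted p = 2.93e-08), among them Fga and Fgg, chains of fibrinogen (−0.82 ± 0.37 and −0.77 ± 0.36, adjusted p = 1 for both). Neutrophil markers were lower beside them (−1.34, 9.17e-05), as were dissociation (−0.52, 0.000587), unfolded protein response (−0.37, 0.000881) and interferon-stimulated genes (−0.21, 0.0109). With an estimated correlation the adjusted p was 0.751 for the MAPK, acute phase, neutrophil and unfolded protein lists, 0.848 for dissociation and 0.951 for interferon-stimulated genes. Adjusted over the list alone, 0 members of these 6 lists were called. Several of these differences rested on WT CCl4 replicate 1, without which the medians were −0.06 for MAPK, −0.01 for acute phase, −0.06 for dissociation and 0.07 for unfolded protein response genes. With any 1 library left out the median ran from −2.20 to −0.65 for neutrophil markers and from −0.29 to −0.03 for interferon-stimulated genes.

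**Figure D5:**
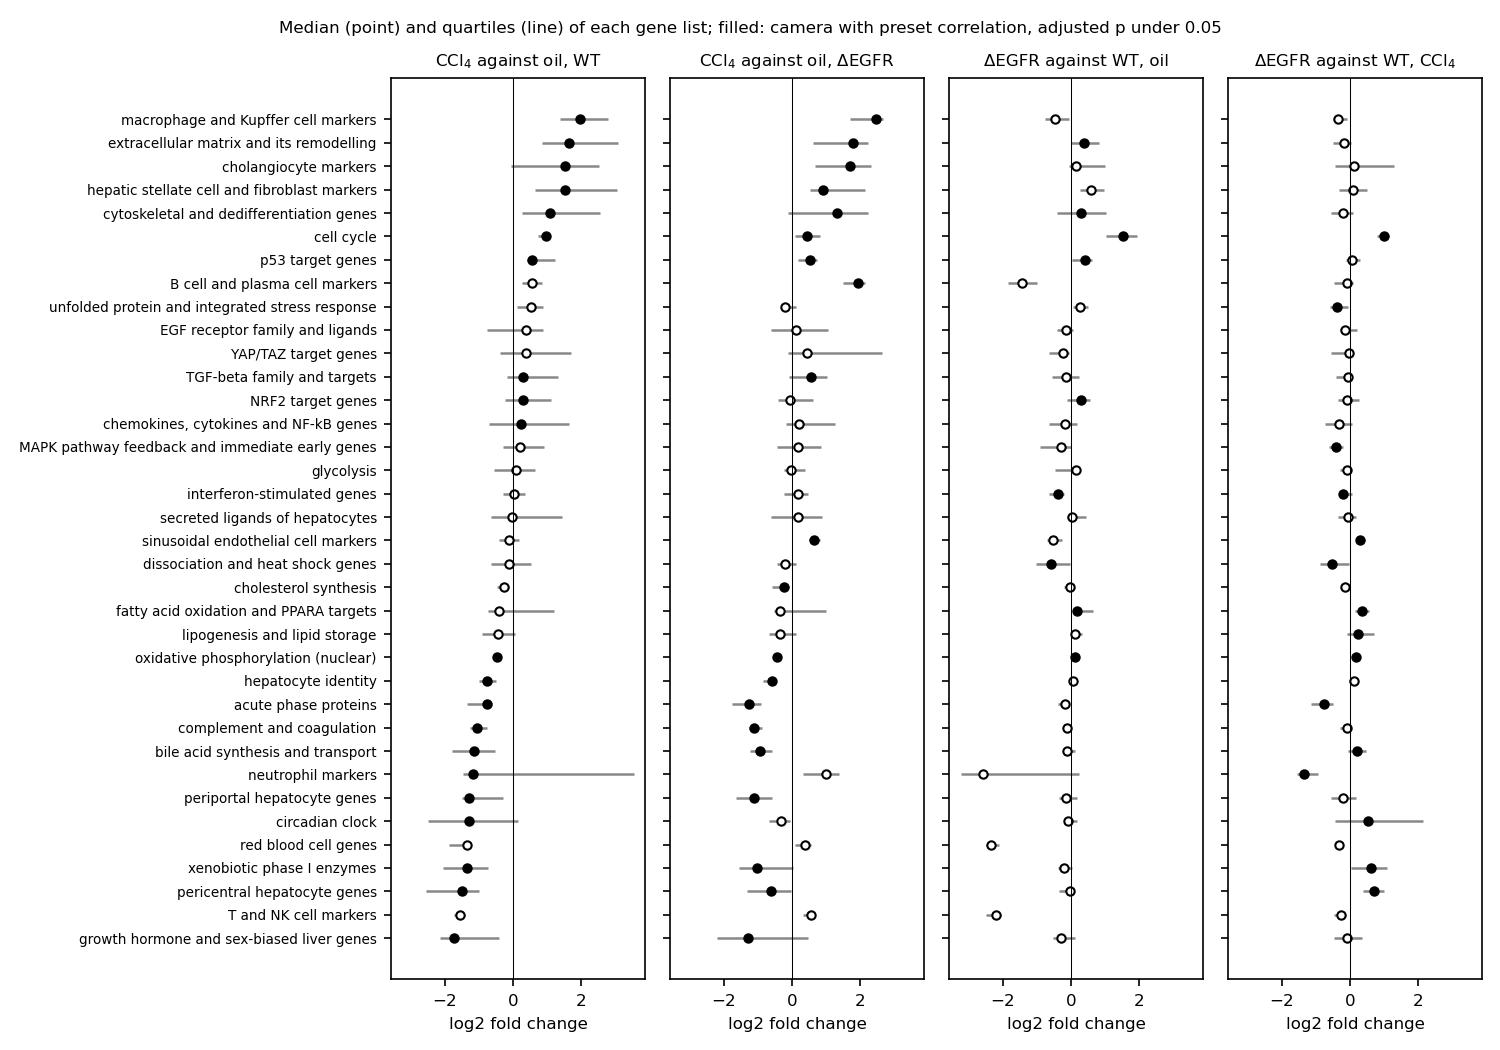
Median log2 fold change (points) and quartiles (lines) of 36 gene lists in 4 comparisons, filled where camera with the preset correlation gave an adjusted p under 0.05. Complement genes had medians of −1.04 and −1.10 with CCl4 in WT and ΔEGFR, and pericentral genes were higher in ΔEGFR CCl4 than in WT CCl4 (median 0.72, camera adjusted p = 5.11e-14, and adjusted p = 0.164 with an estimated correlation).

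The interaction asked whether CCl4 acted differently with the transgene. No gene passed with edgeR, where 568 genes had an unadjusted p under 0.05 against 899 by chance, and leaving out any 1 library gave 0 calls. DESeq2, with 66 unchanged genes among 207 called on simulated data, called 2, Psmd10 (−0.64, adjusted p = 0.0191) and the predicted gene Gm16199 (5.78, adjusted p = 0.00447). Limma called 1, Gm16199 (2.42, adjusted p = 0.0104). These genes were chosen for naming after their values were seen. Cyp2e1 had 2.05 ± 0.61, Cyp1a2 1.47 ± 0.46, Erbb4 3.66 ± 1.11 and Plin2 −1.44 ± 0.33 (adjusted p = 1 for each). Group means of Erbb4 were low, from 0.0865 to 1.87 CPM. Ccnd1 had −2.01 ± 0.61 and Krt8 −2.07 ± 0.67 (adjusted p = 1 for both). All 22 pericentral genes had a positive interaction, with a median of 0.76 (camera adjusted p = 2.55e-08, and adjusted p = 0.593 with an estimated correlation). Phase I (0.76, camera adjusted p = 5.7e-06), clock (0.70, 0.000191) and endothelial genes (0.84, 0.0315) were positive as lists (adjusted p = 0.827, 0.507 and 0.974 with an estimated correlation). NRF2 targets (−0.31, 0.000956), unfolded protein response (−0.38, 0.000191), cell cycle (−0.53, 0.0209), matrix (−0.40, 0.000956), cytoskeletal (−0.10, 0.00626; 0.03 without a scaling factor) and acute phase genes (−0.48, 0.0142) were negative. With an estimated correlation these gave an adjusted p of 0.974, or 0.827 for the unfolded protein response. Without WT mineral oil replicate 1 the endothelial median was −0.40 (adjusted p = 0.385), the cytoskeletal −1.39, the matrix −0.96 and the NRF2 median −0.47, and 24 lists were called. Without WT CCl4 replicate 1 the acute phase median was 0.19, the matrix 0.26 and the unfolded protein response −0.11. The cell cycle median was 0.38 without WT CCl4 replicate 2 and −1.44 without WT mineral oil replicate 4, where the phase I median was 0.22. With any 1 library left out the pericentral median ran from 0.56 to 1.13, the clock from 0.47 to 0.93, the endothelial from −0.40 to 1.59 and the cytoskeletal from −1.39 to 0.19.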

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

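Chosen only after their results were seen were the tests of macrophage against endothelial scores, of pericentral against identity genes, of a wrong label, of blood, of the time of day, of a single library and admixture as reasons for low clock genes and of the score of ΔEGFR calls in WT, while the regroupings that count called genes were planned. Those of the time of day and of a single library replaced earlier tests (signs of all 15 clock genes, and calls kept), of which the latter, fixed before its result was seen, had left a single library open. Of 135 groups of measures checked for a library far from the others, 11 had one, where chance gives about 1 in 20, or 6.8.

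Markers of macrophages rose with CCl4, and the most abundant were high: Lyz2 had 1490 ± 963 CPM in WT CCl4 and 987 ± 267 in ΔEGFR CCl4, against 173 ± 207 and 158 ± 149 in mineral oil. A lower share of hepatocytes, with nothing else changed, would raise markers of every other cell alike. Macrophage minus endothelial scores rose by 2.85 in WT and 2.11 in ΔEGFR (exact permutation p = 0.00408, two-sided). This argues against an equal rise as the whole cause. A lower share alone would also lower hepatocyte genes alike, and pericentral minus identity means changed by −1.06 and −0.37 (exact permutation p = 0.000816, two-sided). Neither test excludes a lower share beside other changes, such as one in which macrophages gained more than endothelial cells. The other-cell score was higher on average with CCl4 in both genotypes, so a lower share stayed open as a part of the cause. Macrophages carried over or recruited with CCl4 may be the source of rising genes: over the 8 mineral oil libraries the median r of these genes with the macrophage score was 0.65, between the markers' own 0.98 and 0.02 for all genes, so the share they explain cannot be told apart from a change inside hepatocytes. Recruitment by injury, a biological explanation the design names, stayed open, and the labels name no sort that would remove macrophages.

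WT mineral oil replicate 1 had 135.5 M counts against 56.9 to 61.9 M in its group (gap 0.936 of the range) and 11.8% mitochondrial counts against 3.3% to 3.5% (gap 0.976). Its CCl4 response score of −5.91, from genes called in ΔEGFR, was nearer to the other WT mineral oil libraries (−7.66 to −6.27) than to WT CCl4 (−3.21 to −1.82). This goes against a CCl4 library under a wrong label, although it lay among CCl4 libraries on the first principal component (−62.4). Those genes came from the model that all libraries share, so they are not independent of its label. With genes called in a fit of the ΔEGFR libraries alone, WT mineral oil ran from −7.25 to −4.14 and WT CCl4 from −2.97 to −1.33. The library thus lay outside the CCl4 range there too, but its nearness to either group was not resolved. A wrong label was not excluded. For an inflamed liver, its acute phase mean of 8.74 lay inside the 8.08 to 9.98 of the other mineral oil libraries. That mean did not rise with CCl4 injury in these data (7.16 to 9.01 in the CCl4 libraries), so it cannot exclude an inflamed liver. Blood carried into the preparation is a candidate explanation, since 4 of the 4 blood cell scores were highest of all 15 libraries there, with S100a9 at 773 CPM and Hbb-bs at 450 CPM, although endothelial markers (6.39) were high too. Beyond inflammation no biological explanation was tested, since the design gives none for a single library.

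Clock-controlled genes were low in the WT CCl4 libraries: Dbp measured 0.742, 1.98 and 1.72 CPM there, 26.5 to 177 in WT mineral oil, 9.92 to 118 in ΔEGFR CCl4, and 2.55 in ΔEGFR mineral oil replicate 3. A different time of day of collection may account for this, and would raise genes of the opposite phase: their mean was 4.45 to 4.90 log2 CPM in WT CCl4 and 1.96 to 3.99 in WT mineral oil (exact permutation p = 0.0571, two-sided), and none of the 5 genes passed alone, so it cannot be told apart from an effect of CCl4 on the clock, which the design names. Such an effect was not seen in ΔEGFR. The mean of 10 genes in the phase of Dbp was 4.10 to 5.40 in ΔEGFR CCl4 and 3.11 to 6.29 in ΔEGFR mineral oil. Loss of hepatocyte transcripts by admixture was argued against, since the 10 genes in the phase of Dbp had a median of −2.32, below the bound of −1.24 set by hepatocyte identity genes. A single library as the cause was argued against: the mean of the 10 genes was 2.43 to 3.34 in all 3 WT CCl4 libraries against 4.31 to 5.84 in WT mineral oil. Leaving out any 1 of the 3 gave a median of −2.86 to −2.14, although of 7 called clock genes 2, 3 and 1 stayed called without replicates 1, 2 and 3.

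The share of mitochondrial counts was also high in ΔEGFR mineral oil replicate 1 (16.9% against 2.2% to 4.6%, gap 0.837). Genes with a single library far from its group were Mup15 in WT mineral oil replicate 2 (3220 CPM against 8.58 to 538, gap 0.835) and Hsd3b5 in replicate 3 (363 against 103 to 140, gap 0.856). In WT mineral oil replicate 4 Vmn2r3 (0.302 CPM against 0, gap 1) and S100g (0.697 against 0 to 0.0669, gap 0.904) stood apart. In ΔEGFR mineral oil replicate 2 Vmn2r3 (2.71 against 0 to 0.0832, gap 0.969) and Aldh1l2 (0.889 against 0.235 to 0.312, gap 0.882) did so. In ΔEGFR mineral oil replicate 4 Abcc4 was lowest (0.522 against 2.21 to 2.38, gap 0.908) and Mup12 highest (52.1 against 2.16 to 10.5, gap 0.832).

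For 10 gene lists the response to CCl4 differed between genotypes by camera with the preset correlation, and for none with an estimated one. Their median interactions were 0.76 (pericentral), 0.76 (phase I), 0.70 (clock), 0.84 (endothelial), −0.31 (NRF2), −0.38 (unfolded protein response), −0.53 (cell cycle), −0.40 (matrix), −0.10 (cytoskeletal; 0.03 without a scaling factor) and −0.48 (acute phase). Without WT mineral oil replicate 1 the cytoskeletal median was −1.39, the matrix −0.96, the NRF2 −0.47 and the endothelial −0.40, and 24 lists were called. Without WT CCl4 replicate 1 the acute phase median was 0.19 and the matrix 0.26, and without WT CCl4 replicate 2 the cell cycle median was 0.38.

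Other splits of the same libraries tested the counts. For CCl4 in WT chance could not be excluded by the count: 2 of 35 splits gave as many genes as the real 2250, and the other one gave 5035. It set WT mineral oil replicate 1 with the CCl4 libraries (other-cell scores 3.27 to 4.11) against the other WT mineral oil libraries (−0.47 to 2.18), which points to a structure of the samples along other-cell transcripts. A score of genes called in a fit of the ΔEGFR libraries alone was −2.97 to −1.33 in WT CCl4 and −7.25 to −4.14 in WT mineral oil (exact permutation p = 0.0571, two-sided), which left chance open too. With ΔEGFR calls of the model that WT libraries share the exact permutation p was 0.0286, but those genes are not independent of the WT grouping. For CCl4 in ΔEGFR only the real split gave as many genes (1 of 35 splits, real 746, highest other 0). This argues against chance as far as 35 splits can, since 1 of 35 is the smallest share possible. The real groups were also parted by other-cell scores (3.07 to 3.88 with CCl4, −0.29 to 2.88 in mineral oil). The count therefore cannot be told apart from that structure. For the other 3 comparisons the real count was 0, which every split meets, so the splits could not test chance (35 of 35 for genotype in mineral oil, 35 of 35 for genotype in CCl4 and 100 of 100 for the interaction, highest other 1517, 0 and 31). The split with 1517 parted libraries with other-cell scores of 2.08 to 4.11 from those with −0.47 to 1.99, again a structure of the samples.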

How the results depend on the processing

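The results were recomputed with alternatives fixed in advance and with every added alternative chosen after seeing the data (no scaling factor, depth class, lists without WT mineral oil replicate 1, list medians under other scalings and list medians without each library). For CCl4 in WT the 2250 called genes became 1457 without a low-count filter, 533 with only the groups compared, 522 against a fold of 1.5, 751 with the marker covariate and 3611 with DESeq2 (575 to 5111 over left-out libraries). For CCl4 in ΔEGFR the 746 became 470, 1286, 84, 80 and 2399 in the same order, 2268 with limma, 1180 without scaling and 1643 with depth class (75 to 2145). The larger count in WT than in ΔEGFR was reversed with only the groups compared. Counts of 0 became 9, 1 and 2 with DESeq2 (genotype in mineral oil, in CCl4, interaction) and 1 with limma (interaction), and were 0 to 0 over left-out libraries. Genes called in both genotypes, 270 higher and 352 lower, became 825 and 809 with DESeq2 (1634 in all), 1512 and 104 with limma, 761 and 152 without scaling, 420 and 651 with depth class, 147 and 229 without a low-count filter, 91 and 118 with only the groups compared, 41 and 37 against a fold of 1.5 and 29 and 37 with the marker covariate (34 to 849 and 40 to 1003 over left-out libraries). Adjusted p of Egfr ran over left-out libraries from 0.00542 to 0.0567 (CCl4 in WT), 0.00734 to 0.0499 (CCl4 in ΔEGFR), 0.714 to 0.995 (genotype in mineral oil), 1 to 1 (genotype in CCl4) and 0.963 to 1 (interaction); it was 0.0502 for CCl4 in ΔEGFR with the marker covariate. The sign of Egfr for genotype in mineral oil reversed with depth class (adjusted p = 0.585) and without WT mineral oil replicate 3 (0.966) or ΔEGFR mineral oil replicate 3 (0.925). Alb for CCl4 in WT reversed with limma (adjusted p = 0.966), and Ccnd1 for CCl4 in ΔEGFR with the marker covariate (adjusted p = 0.973). With an estimated correlation 0 lists were called in each comparison; fry called 12 (CCl4 in WT), 3 (CCl4 in ΔEGFR) and 0, 0 and 0. Without WT mineral oil replicate 1 camera called 27, 20, 22, 16 and 24 lists in the 5 comparisons, and 3 of the lists called with all libraries reversed in their test: dissociation (adjusted p = 0.0912) and oxidative phosphorylation genes (0.272) for genotype in mineral oil, and endothelial markers for the interaction (0.385). The median of interferon-stimulated genes for genotype in mineral oil changed from −0.39 to 0.01, and medians of uncalled T and NK cell, neutrophil and red blood cell markers changed sign for genotype in mineral oil (to 1.82, 2.34 and 2.82) and for the interaction (to −2.12, −3.18 and −3.15). Without WT CCl4 replicate 1 the acute phase median changed from −0.75 to −0.01 for genotype in CCl4 and from −0.48 to 0.19 for the interaction. For all these results the cause was not tested, except that a test against a fold asks for larger changes. Of the 76 selected genes called for CCl4 in WT, 76 kept the call with DESeq2, RLE and upper-quartile factors and 47 with the marker covariate. Of the 52 selected for CCl4 in ΔEGFR, 52, 50, 46 and 19 did. Depth limits genes with few counts, such as Gpc3 and Cdh17 in mineral oil.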

Other observations

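These values were chosen only after the results were seen, and no tests were made on the gene families beyond the calls of each gene. Of 20 Mup genes, which encode urinary proteins, 13 fell with CCl4 in WT (median −3.89) and 13 in ΔEGFR (median −4.16), with negative medians under every scaling tried. Of 16 Ugt genes, which conjugate toxins and bilirubin, 11 fell in WT (median −1.26) and 9 in ΔEGFR (median −1.32). Of 13 Ms4a genes, membrane proteins of immune cells, 4 rose in WT (median 1.47) and 2 in ΔEGFR (median 2.04). Of 20 Serpina protease inhibitors 1 rose and 4 fell in WT (median −0.96), and 2 fell in ΔEGFR (median −1). Mup and Ugt paralogs share near-identical sequence, so counts of single members depend on how reads were apportioned.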
